A study of Rattus norvegicus with 4 samples.

How the data were processed

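Liver RNA of 4 untreated male Sprague-Dawley rats aged 10 to 12 weeks was measured, each rat on its own Affymetrix expression array. All 4 samples form 1 group, so no groups were compared. The 4 livers came from separate animals, but each animal had 1 array, and a difference between animals cannot be separated from a difference between arrays.

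The deposited values are log2 signals of 15923 probe sets, running from 5.98 to 15.07. Per the submitters' processing notes, R 2.4.1, affy 1.12.2, GCRMA and RMA were used, with no order or role given. Which of GCRMA and RMA gave the deposited values is therefore not given in the sources used here. The medians of the 4 arrays were all 8.11 and the upper quartiles lay between 8.69 and 8.70, so the arrays had been put on a common scale before deposit. The array type is RAE230A per the scanner settings, while the labels' protocol names RAE230-2, and the annotation used here covers the probe sets of the values. All 4 arrays were processed on 1 day with 1 lot, on fluidics station 1 and modules 1 to 4, so no batch could be fitted. No unit other than log2 signal was used. Signals of different probe sets depend on their probes and are not relative amounts of transcript. The background call, the choice of a gene's brightest probe set, the rule for named genes and the differences between 3' and 5' ends nevertheless compare signals between probe sets, so they describe signal, not amount.

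Of the 15923 probe sets, 12789 carried 1 gene symbol, 312 carried several, and 2822 carried none. The array has 57 control probe sets, of which 6 carry a symbol, so 2771 of those without one are not controls. Only those with 1 symbol were named. Of these 12789, 12754 were matched by gene number to the gene table of the rat assembly GRCr8, used for names only. Each of the 10412 genes was represented by its probe set with the highest mean, and 1870 genes had more than 1 probe set. The 36 gene lists, 1 of them the background list, were fixed before the data were examined. Older symbols in the lists were matched through synonyms, except Ms4a1 and Crisp1, a choice made after the annotation was read but before any value was seen.

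The background level was the 95th percentile of the mean signals of 88 probe sets of 66 genes of brain, muscle, testis and eye. A gene was above background if its mean over the 4 rats exceeded that level. Lists were compared with all other named genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 35 lists. Genes that varied between rats were sought with limma 3.58.1 in R 4.3.3, by an F test of the residual variance with 3 degrees of freedom against a robust trended prior, at an adjusted p of 0.05. The spread of a list was the median between-rat SD of its genes above background, set against 10000 random lists matched on mean signal in 10 classes, with two-sided permutation p-values, for lists with at least 5 such genes. Genes of a list move together, so these p-values are too small and describe these 4 rats. Deviations of the 2 brightest probe sets of a gene were correlated across genes, against 10000 random pairings. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.

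The methods were tested on simulated data. For the variance test, 200 of 2088 simulated genes had an enlarged SD. Without flat genes, it recovered 7.46% of genes with a 4-fold SD, 56.7% with an 8-fold SD and 90.9% with a 16-fold SD, with 0 false calls. With 25% of the unchanged genes flat, it recovered 0% at each size. For the list spread, 7% of 100 random lists of 12 genes had a permutation p under 0.05, and 87.5% of 40 lists with tripled SDs did. For the probe set correlation, independent simulated deviations gave r = -0.02 and deviations with a true r of 0.5 gave r = 0.51, both over 1870 genes.

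Genes were named by a rule fixed before the data were examined. It took 29 sentinel genes, the 2 members of each list with the highest mean, the member of each drug metabolism list with the largest SD, the 12 variable genes with the smallest p, the 3 extreme members of each list with a called spread, and the 5 brightest-tenth genes with the smallest SD. No gene was called variable, so the 12 genes with the largest SD were named after their values were seen. All members above background of 6 lists (P450 families 1 to 4, nuclear receptors, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, and glucocorticoid, fasting and growth hormone response) were also added after values were seen. Of the sentinels, 5 had no probe set of their own and were not analysed here.

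Alternatives fixed in advance covered the background level, the probe set chosen per gene, the scaling, the prior, the measure of spread, the thresholds and leaving out each rat. A block for the scan day was planned and not run, since there was 1 day. A list's alternative counts as changed only where it crossed its test's threshold, and as reversed where its value changed sides and either setting passed the test, even if the other did not. Leaving out flat probe sets, defined as those with a range under 0.001 log2 units over the 4 arrays, and leaving Myh1 out of the background list were chosen after seeing the data.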

Results

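The series measured liver transcripts in 4 untreated male rats, each on its own array. Its title concerns proteins of the endoplasmic reticulum that detoxify drugs, and the protein measurements are not analysed here. With 1 group, the design asks which genes gave a signal above background and how much that signal differed between rats. Values are mean log2 signal ± SD over n = 4 rats, and the number of arrays limits their precision.

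The background level was a log2 signal of 9.05, and 2618 of 15923 probe sets lay above it, with 2598 to 2646 on the single arrays. At gene level, 2088 of 10412 genes, or 20.1%, were above background. The level rests on few probe sets. Of the 5 probe sets assigned to Myh1, a myosin of skeletal muscle, 4 had mean signals between 10.04 and 11.49, and without Myh1 the level was 8.41 and 5623 probe sets lay above it. With the 90th percentile 5877 probe sets lay above background, and with the 98th percentile 665 did.

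Of 11 drug metabolism lists, which include transporters and nuclear receptors, 5 were above background more often than other genes. Cytochromes P450 of families 1 to 4, which oxidise drugs and fatty acids, were above background for 27 of 40 genes (Fisher's exact test, adjusted p = 6.74e-10). Examples were Cyp2c11, the main male-specific P450 of rat liver, at 13.54 ± 0.08, Cyp2e1, which oxidises ethanol, at 13.40 ± 0.09, and Cyp1a2 at 12.69 ± 0.30. Their electron donors were above background for 7 of 8 genes (adjusted p = 0.00023, exact test), among them cytochrome b5 (Cyb5a) at 12.45 ± 0.03 and P450 reductase (Por) at 9.38 ± 0.28. Glutathione transferases were above background for 16 of 19 genes (adjusted p = 1.98e-08, exact test), with the microsomal Mgst1 at 13.65 ± 0.05 and Gstm1 at 12.47 ± 0.22. Carboxylesterases reached 4 of 5 genes (adjusted p = 0.0139, exact test), and aldehyde, alcohol and aldo-keto enzymes 29 of 55 (adjusted p = 3.55e-07, exact test).

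**Figure D1:**
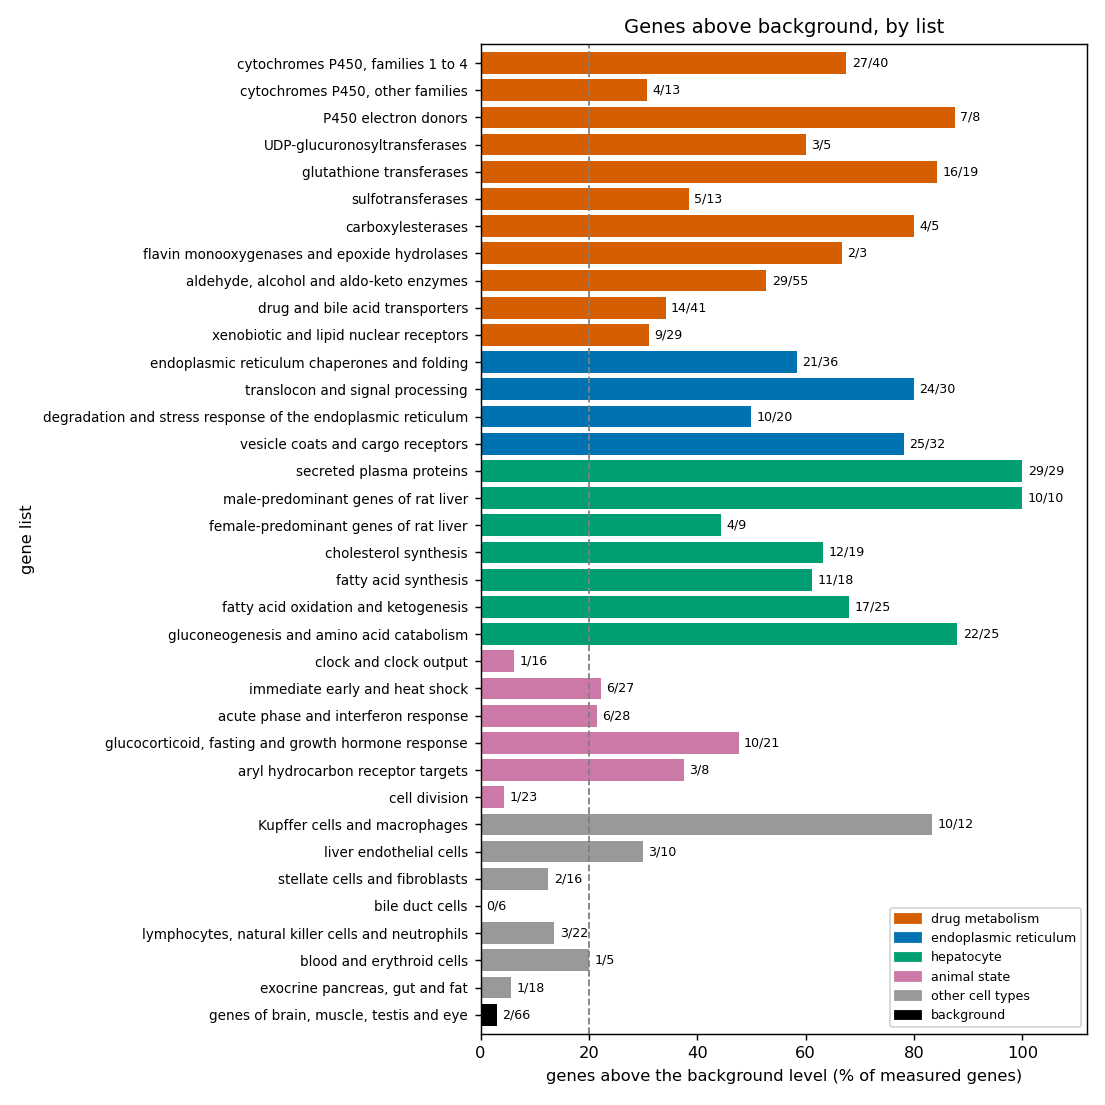
Percent of the measured genes of each list whose mean log2 signal over 4 rats was above the background level of 9.05, with the count at the end of each bar and colours for the kind of list. The dashed line marks 20.1%, the share over all 10412 genes, and secreted plasma proteins reached 29 of 29 while the background list had 2 of 66.

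The other 6 drug metabolism lists did not pass the test at the 95th percentile with all probe sets used. Drug and bile acid transporters had 14 of 41 genes above background (adjusted p = 0.0601, exact test), nuclear receptors 9 of 29, sulfotransferases 5 of 13, UDP-glucuronosyltransferases 3 of 5, P450s of other families 4 of 13, and flavin monooxygenases and epoxide hydrolases 2 of 3. At the 98th percentile, transporters (adjusted p = 0.0347, exact test), sulfotransferases (0.00902), UDP-glucuronosyltransferases (0.0473) and P450s of other families (0.0474) passed, and at the 90th percentile nuclear receptors did (0.04). Without probe sets of the suffixes s, x and a, transporters passed too (35.9%, adjusted p = 0.0496, exact test), as nuclear receptors did without Myh1 (0.0253). Members with signal included the bile acid importer Slc10a1 at 12.07, Ephx1, the microsomal epoxide hydrolase, at 12.61 ± 0.47, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 10.03 ± 0.23. The aryl hydrocarbon receptor Ahr had a signal of 8.07 and its target Cyp1a1 8.02, both below background. The constitutive androstane receptor Nr1i3 had 8.61 ± 0.16, which was below background too. Without Myh1 the level was 8.41, which Nr1i3 exceeded and Ahr and Cyp1a1 did not. These signals exceeded those of 27 control probe sets for Bacillus transcripts (6.48 to 7.75), so a signal below background does not show that a transcript was absent. The pregnane X receptor Nr1i2, at 9.06, lay at the background level. Values without an SD are those of flat probe sets, equal to within 0.001 on all 4 arrays. Of 24 sentinel genes with a probe set of their own, 21 were above background.

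**Figure D2:**
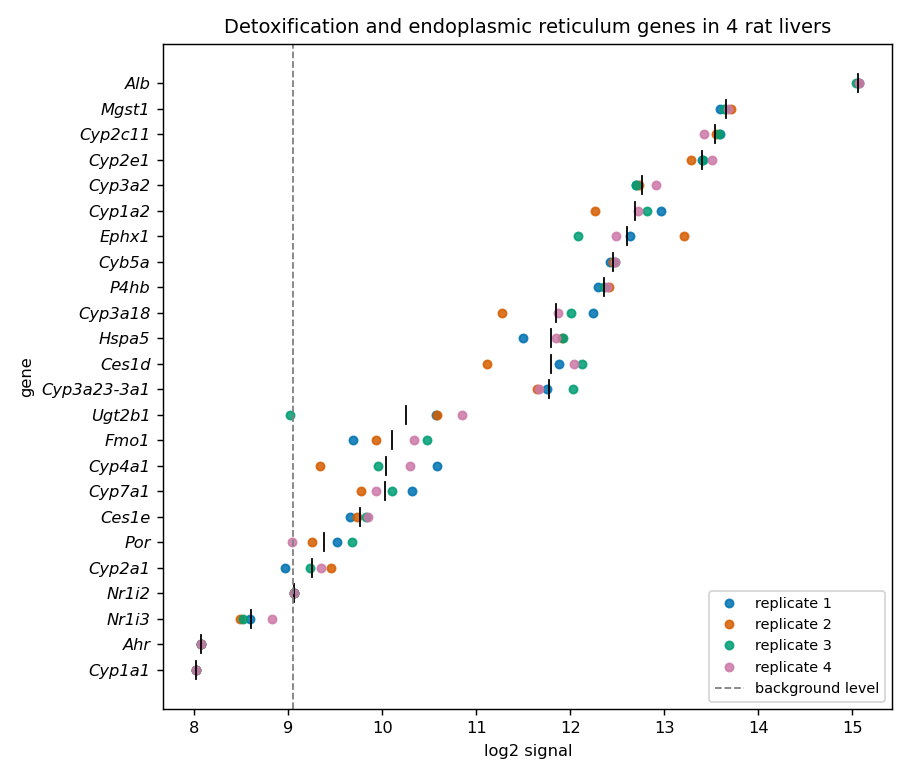
Log2 signal of 24 sentinel genes in each of 4 rats (points, 1 colour per rat) with their mean (black line) and the background level of 9.05 (dashed line). Ugt2b1 in replicate 3 stood at 9.02 against 10.57 to 10.84 in the other rats.

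All 4 lists of the endoplasmic reticulum were above background more often than other genes. Translocon and signal processing genes, which bring new proteins into the organelle, had 24 of 30 genes above background (adjusted p = 2.35e-11, exact test), with Tram1 at 12.06 ± 0.04. Vesicle coats and cargo receptors had 25 of 32 (adjusted p = 2.35e-11, exact test), chaperones and folding enzymes 21 of 36 (adjusted p = 1.71e-06, exact test), and degradation and stress response genes 10 of 20 (adjusted p = 0.00612, exact test; 10% and adjusted p = 0.358 at the 98th percentile). The chaperone Hspa5 had a signal of 11.79 ± 0.20, the disulfide isomerase P4hb 12.36 ± 0.05 and calreticulin (Calr) 12.08 ± 0.04.

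Hepatocyte lists passed the test in 6 of 7 cases. Secreted plasma proteins were above background for 29 of 29 genes (adjusted p = 1.74e-19, exact test), with albumin (Alb) at 15.06 ± 0.02. Genes listed as male-predominant were above background for 10 of 10 (adjusted p = 4.52e-07, exact test). Those listed as female-predominant were for 4 of 9 (adjusted p = 0.144, exact test), with Cyp2c7 at 13.21 ± 0.21 and Sult1e1 at 12.27 ± 0.23. All rats were male, so the assignment of these genes to a sex was not tested. Gluconeogenesis and amino acid catabolism had 22 of 25 genes above background (adjusted p = 8.7e-12, exact test), fatty acid oxidation and ketogenesis 17 of 25 (adjusted p = 1.04e-06, exact test), cholesterol synthesis 12 of 19 (adjusted p = 0.000147, exact test; 10.5% and adjusted p = 0.346 at the 98th percentile) and fatty acid synthesis 11 of 18 (adjusted p = 0.000402, exact test).

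Of the 6 lists of animal state, the glucocorticoid, fasting and growth hormone response passed, with 10 of 21 genes (adjusted p = 0.00901, exact test), but not without replicate 2 (adjusted p = 0.0501, exact test). The call was also lost with the median of a gene's probe sets (0.0735), without probe sets of the suffixes s, x and a (0.0718) and at the 98th percentile (0.141). Clock genes had 1 of 16 above background, immediate early and heat shock genes 6 of 27, acute phase and interferon genes 6 of 28, aryl hydrocarbon receptor targets 3 of 8 and cell division genes 1 of 23. Of 7 lists of other cell types, Kupffer cells and macrophages passed with 10 of 12 genes (adjusted p = 1.45e-05, exact test), among them the Kupffer cell receptor Clec4f at 10.51 ± 0.24. At the 98th percentile 0% of them were above background (adjusted p = 1, exact test). Endothelial cells had 3 of 10, stellate cells and fibroblasts 2 of 16, bile duct cells 0 of 6, lymphocytes, natural killer cells and neutrophils 3 of 22, blood cells 1 of 5, and exocrine pancreas, gut and fat 1 of 18.

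The median between-rat SD of genes above background was 0.053 log2 units, and 0.0737 without flat probe sets. An SD over 0.5 was found in 27 genes. The F test of limma called 0 genes variable, with 13 at an unadjusted p under 0.05 and a smallest adjusted p of 0.264. This count says little, because 495 of the 2088 genes, or 23.7%, had values equal to within 0.001 on all arrays, and the test recovered 0% of simulated variable genes when 25% of the unchanged genes were flat. Without flat probe sets it called 0 of 1593 genes too, with 46 at an unadjusted p under 0.05. There the smallest unadjusted p of the F test was 0.0105 and the smallest adjusted p 0.919. Yet Mt2A had an SD of 1.43, against a median SD of 0.0646 in the prior. The prior had 1.45 degrees of freedom, against 3.56 in the simulation without flat genes, so the simulated recovery does not carry over. The count without flat probe sets therefore says little either.

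The genes with the largest SD, chosen after their values were seen, included the metallothionein Mt2A at 10.52 ± 1.43, which ran from 8.94 to 12.33. Others were Slc25a25, a mitochondrial carrier, at 9.16 ± 0.94, Osgin1 at 10.72 ± 0.88, the phosphatase Dusp1 at 9.10 ± 0.82, the kinase Sgk1 at 9.37 ± 0.75 and Ugt2b1 at 10.25 ± 0.83. The rule for the smallest SD named Cmas, Ncln, Sdha, Serping1 and Strap, all flat, so these SDs do not measure the animals.

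Of 21 lists tested, 6 differed between rats more than random lists of the same signal. The random lists drew flat genes too, which lowers their value. With flat probe sets left out, all 6 still passed (adjusted p from 0.0028 to 0.0341, permutation), cholesterol synthesis with 0.339 against 0.082. Cholesterol synthesis genes had a median SD of 0.339 against 0.0656 in random lists (adjusted p = 0.00105, permutation), with Dhcr7 at 10.07 ± 0.66, Idi1 at 9.07 ± 0.51 and Insig1 at 10.28 ± 0.47. It was 0.0872 without replicate 2 (adjusted p = 0.345, permutation) and 0.225 without replicate 1 (adjusted p = 0.00252, permutation). P450s of families 1 to 4 had 0.186 against 0.0614 (adjusted p = 0.00105, permutation), led by the fatty acid hydroxylases Cyp4a3 at 10.56 ± 0.62 and Cyp4a1 at 10.04 ± 0.54, and Cyp3a9 at 9.26 ± 0.56. Glucocorticoid, fasting and growth hormone genes had 0.255 against 0.0589 (adjusted p = 0.00105, permutation), and 0.476 without probe sets of the suffixes s, x and a. Fatty acid synthesis had 0.223 against 0.0657 (adjusted p = 0.00252, permutation), with Scd at 11.20 ± 0.58, and gluconeogenesis and amino acid catabolism 0.139 against 0.0672 (adjusted p = 0.0102, permutation), with Tat at 10.36 ± 0.66. Nuclear receptors had 0.185 against 0.0396 (adjusted p = 0.0028, permutation), and 0.0973 without replicate 4 (adjusted p = 0.115, permutation).

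Secreted plasma proteins were the 1 list with less spread, 0.0279 against 0.0658 (adjusted p = 0.00105, permutation), but 7 of their 29 genes were flat, and without flat probe sets the value was 0.0576 (adjusted p = 0.27, permutation). In that setting vesicle coats and cargo receptors were the list with less spread (0.0383, adjusted p = 0.0115, permutation), and acute phase and interferon genes had more (0.249, adjusted p = 0.0341, permutation). The remaining 14 lists did not pass the test, though 7 of them passed in another setting, fatty acid oxidation and ketogenesis in 6 of 14 settings. Without replicate 1, 11 lists passed instead of 7.

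**Figure D3:**
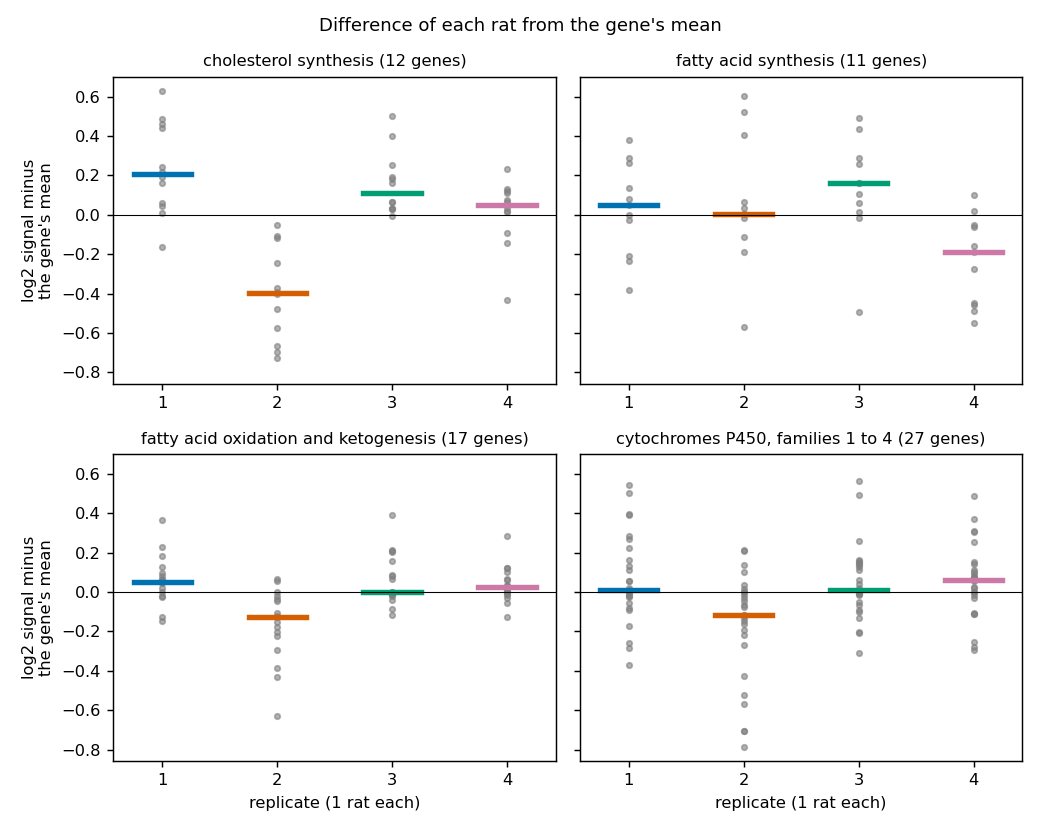
Log2 signal of each gene above background minus its mean over the 4 rats (grey points), with the median per rat (coloured line), for 4 gene lists. The median of cholesterol synthesis genes was -0.40 in replicate 2, where 11 of 12 genes had their lowest signal.

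Of 21 lists with at least 5 genes that were not flat, 10 had more than 50% of these genes lowest in 1 rat, 3 of them in replicate 1, 4 in replicate 2 and 3 in replicate 4. No chance level was computed for the counts in this paragraph. Genes of a list move together and short lists pass 50% easily, so the counts only describe these 4 rats. Besides cholesterol synthesis, 13 of 25 P450 genes of families 1 to 4 (median deviation -0.11), 14 of 27 aldehyde, alcohol and aldo-keto enzymes (-0.06) and 13 of 16 genes of fatty acid oxidation and ketogenesis (-0.14) were lowest in replicate 2. Lowest in replicate 1 were 13 of 17 chaperones of the endoplasmic reticulum (-0.12), 11 of 18 translocon genes (-0.07) and 7 of 11 glutathione transferases (-0.06). The beta-actin signal at the 3' end exceeded that at the 5' end by 0.85 log2 units in replicate 1, against 0.54 to 0.66 in the other rats. For Gapdh this difference was smallest in replicate 1 (0.48 against 0.52 to 0.54). Actin and Gapdh thus went opposite ways, and no cause is drawn from them. Lowest in replicate 4 were 6 of 8 nuclear receptors (-0.17), 6 of 11 genes of fatty acid synthesis (-0.19) and 3 of 5 immediate early and heat shock genes (median -0.07, but mean 0.19). More than 50% of the genes were highest in 1 rat in 7 lists. In replicate 3 these were 6 of 8 nuclear receptors (0.14), 12 of 18 translocon genes (0.06), 5 of 8 degradation and stress response genes of the endoplasmic reticulum (0.10), 6 of 11 genes of fatty acid synthesis (0.16) and 12 of 20 of gluconeogenesis and amino acid catabolism (0.09). The others were 5 of 9 male-predominant genes in replicate 1 (0.05) and 6 of 8 Kupffer cell genes in replicate 2 (0.10), among them Clec4f (10.82) and C1qa (10.39).

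With flat genes included, Kupffer cell genes had median deviations of -0.10, 0.07, 0.04 and -0.02 in replicates 1 to 4, the 2 stellate cell genes 0.01, 0.22, -0.41 and 0.18, and the 3 endothelial genes 0.00, -0.03, 0.16 and 0.00. The collagen Col3a1 was at 11.15 in both replicates 2 and 4 and at 10.23 in replicate 3. In single rats, 9, 9, 7 and 4 genes differed by at least 1 log2 unit from the median of the other 3, in replicates 1 to 4. Deviations of the 2 brightest probe sets of a gene correlated across 1870 genes (r = 0.378, permutation p = 0.0001, the smallest that 10000 pairings can give), where the highest random value was 0.1. Where both probe sets were above background, r was 0.695 over 166 genes.

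**Figure D4:**
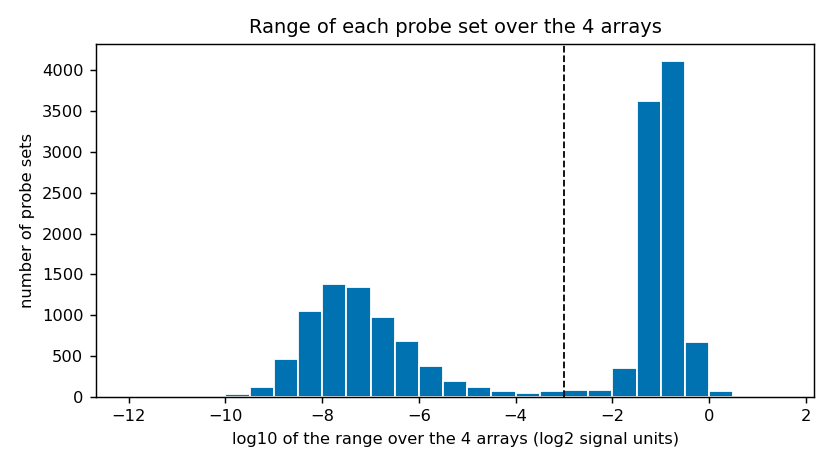
Number of probe sets by the log10 of their range over the 4 arrays, with the limit of 0.001 log2 units as a dashed line. There were 2 separate groups, and 6923 of 15923 probe sets lay below the limit.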

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

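The tests of single probe set noise and of chance among lists were fixed before their results were seen. The other tests in this part were chosen after the results were seen. The hepatocyte test replaced 2 narrower ones, and the whole-array test an earlier one, whose values were known. A test of RNA quality was added and withdrawn.

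Among 182 sets of 4 values, 13 had 1 rat far from the other 3, where chance gives about 5%. Far means a large gap relative to the range of the 4 values, so small differences can count. The sets overlap, since lists hold some of the named genes, and an excess over chance was not tested. Several of the genes were named only after their values were seen. In replicate 2 the log2 signals of Decr1 (10.13), Fdft1 (9.55), Msmo1 (9.64) and Sult1e1 (11.92) lay below the other rats. Hadh (11.98 against 11.91) lay above them. In replicate 1, Hpd (12.74 against 12.77) and Ubd (8.43 against 9.85 to 10.02) lay below the others. Ugt2b1 in replicate 3 (9.02) lay below the others and Cyp3a2 in replicate 4 (12.91) above them. The mean deviation of a list stood apart in replicate 2 for P450 families 1 to 4 (-0.17), sulfotransferases (-0.11) and fatty acid oxidation and ketogenesis (-0.17), and in replicate 1 for glutathione transferases (-0.056). Outside the named genes, 188 probe sets without a gene symbol and 141 with several symbols were above background.

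Cholesterol synthesis genes were lower in replicate 2, with a median deviation of -0.40 log2 units, while Kupffer cell genes, flat ones included, had a median of 0.07 there, stellate cell genes 0.22 (0.18 in replicate 4) and endothelial genes -0.03. Noise of single probe sets is argued against by 5 of 5 other probe sets of these genes, lowest in replicate 2 (binomial exact p = 0.000977). They include that of Srebf2 (deviation -0.08), whose brighter probe set was lowest in replicate 1 instead (9.66 against 9.72 in replicate 2). If only those above background count, which leaves Srebf2 out, 3 of 3 were lowest there (binomial exact p = 0.0156, a choice made after seeing the data). Independent variation of single genes is argued against by 0 of 10000 random lists with as large a deviation. Random lists draw unrelated genes, some of them flat, while genes of a list move together and none of these was flat. They therefore do not decide on a chance difference of 1 group of genes in 1 rat. A smaller share of hepatocytes as the whole source is argued against by the 176 other genes of hepatocyte and drug metabolism lists. Their median was -0.044, with an SD of 0.22 over genes. Narrower versions gave 0.015 for plasma proteins and -0.062 for gluconeogenesis and amino acid catabolism, flat genes left out. Still, 113 of the 176 genes (64.2%) were below their mean in replicate 2, so a small part stays open. A lower signal of the whole array that remained after the scaling before deposit would lower other genes alike. The same 176 genes argue against such a remainder as the whole source. A fall of the whole array that the scaling removed cannot be seen in them. After quantile normalization the deviation of the cholesterol list was still -0.37, and 0 of 10000 random lists had as large a deviation (largest 0.177). The arrays were on a common scale before deposit, and this step moved no gene above background by more than 0.0595 log2 units in replicate 2. A small part from the whole array therefore stays open. A general low level of hepatocyte metabolism stays open too. Of 2 lists checked, 1 was lowest in replicate 2, and 9 of 12 lists had a median below 0. A stricter bound, loosened after the value was seen, would have excluded such a general low level. The series has 1 group, so no biological difference named by its design could be tested.

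Flat probe sets made up 43.5% of the array. Low signal alone is argued against by the 23.4% of probe sets above background that were flat. Among 166 genes with both bright probe sets above background, 62 had a flat one. Equal transcripts in the 4 rats are argued against by 51 of these 62 (82.3%), whose other bright probe set was not flat. Those other probe sets had a median SD of 0.0592. A summarisation that set small differences to near 0 may be the source, since 1.76% of probe sets had a range between 0.0001 and 0.01, which leaves 2 separate classes, but the method is not given in the sources used here.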

How the results depend on the processing

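Leaving out flat probe sets and leaving Myh1 out of the background list were chosen after seeing the data. No paired analysis was possible because there is 1 group, and a block for the scan day was not run because there was 1 day. Arrays give no read depth, and the background level limits which genes count as measured. The number of probe sets above background moved from 2618 to 5877 with the 90th percentile, 665 with the 98th, 15923 with a log2 value of 6 and 5623 without Myh1, and was 2577 to 2663 with 1 rat left out. With a log2 value of 6 all genes were above background and the exact test of lists could not be run. Lists above background more often than other genes numbered 16 to 17 with 1 rat left out and 16 to 18 otherwise. With the 90th percentile and without Myh1, 3 more lists passed because they were above background less often (cell division 17.4%, lymphocytes 18.2%, exocrine pancreas, gut and fat 11.1%), and with the median of probe sets cell division did (0%). The Kupffer list lost its call at the 98th percentile, with 0% of its genes above background (adjusted p = 1, exact test), which shows no opposite direction. The limma F test called 0 genes in all settings run, with 0 to 1484 genes at an unadjusted p under 0.05. The number of lists with a called spread moved from 7 to 13 with the 90th percentile, 12 with a log2 value of 6 and 14 without Myh1, and was 7 to 11 with 1 rat left out. With a log2 value of 6 the median SD was 0.173 for cholesterol synthesis, 0.121 for fatty acid synthesis and 0.0551 for nuclear receptors, which still passed. The number of lists was 8 without flat probe sets and 5 with the mean log2 variance. Plasma proteins were lost with quantile normalization (adjusted p = 0.0582, permutation), with log2 variance (0.157) and without flat probe sets (0.27), nuclear receptors and gluconeogenesis with log2 variance (0.187 and 0.294). Genes departing in replicates 1 to 4 numbered 42, 36, 34 and 31 at 0.58 log2 units, and 0, 0, 0 and 1 at 2 log2 units. Without a background filter they were 14, 13, 12 and 7. The correlation between probe sets was 0.361 to 0.406 with 1 rat left out. The causes of these changes were not tested.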

Other observations

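The test in this part was chosen after the values were seen. Sterol and fatty acid synthesis share regulation by SREBP proteins, and a hypothesis was that both lists shift together between rats. Their median deviations had the same sign in 2 of 4 rats, not in all 4 as the hypothesis predicted. In replicates 1 to 4 they were 0.21, -0.40, 0.11 and 0.05 for sterol genes. For fatty acid genes they were 0.05, 0.01, 0.16 and -0.19. Rejecting the hypothesis required a clear move of both lists in opposite directions, which cannot occur where 1 list stays near 0. This rule therefore could not reject the hypothesis, although its prediction was not met. In replicate 2 the sterol list had a median of -0.40 and the fatty acid list 0.01, so the 2 lists as wholes did not fall together there. There 2 genes of the fatty acid list, Srebf1 (11.53) and Scd (11.80), had their highest signals. Another 3 genes of that list, Acss2 (8.93), Fads1 (11.03) and Fads2 (9.88), had their lowest signals in replicate 2, as Insig1 (9.62) of the sterol list did.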
